A study of Bacteroides thetaiotaomicron VPI-5482 with 6 samples.

How the data were processed

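The series measured messenger RNA of Bacteroides thetaiotaomicron VPI-5482, an anaerobic bacterium of the human gut that breaks down many glycans, by RNA sequencing of 6 libraries. Of these, 3 came from cultures with glucose (5 mg/ml) and 3 from cultures with bovine alpha-1-acid glycoprotein (AAGP, 10 mg/ml), a serum glycoprotein that carries complex N-glycans, as the carbon source of a minimal medium. Per the labels' protocols, triplicate tubes of 5 ml were inoculated from 1 overnight culture in rich medium and harvested in mid exponential phase at an optical density of about 0.8. The replicates are therefore separate tubes that share an inoculum, and the p-values measure the spread between such tubes. The sample titles give glucose in mg/ml, whereas the growth protocol gives the same figure in mg/l, and the titles were followed here.

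Per the labels' protocols, RNA with integrity numbers between 5.9 and 7.1 and an input of 1 ug was depleted of ribosomal RNA with a bacterial Ribo-Zero kit. Strand-specific libraries were made with dUTP in the second strand, amplified for 15 cycles and sequenced as paired ends of 75 bp. The molecule label names polyA RNA, while the protocol describes ribosomal depletion. The submitters' processing notes name FastQC 11.2, Bowtie2 2.2.4 and featureCounts. The genome build, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The deposited table holds raw counts, whole-number read counts per gene that the authors had not normalised, for 4831 genes with their replicon, start, end and strand.

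Of the 4831 genes, 38 lie on the plasmid and 6 are structural or other noncoding RNA genes, and no ribosomal RNA genes were recognised by identifier. Coordinates are those of the deposited table, counted from 1, and 793 genes overlap another gene in the table. Reads in such overlaps can be shared or lost, and whether counting used strand is not given in the sources used here. This concerns BT_0455, BT_0456, BT_0459, BT_0401, BT_1353 and BT_2119 among the genes named. An annotation table of another strain's assembly matched 0 of the 4831 identifiers and was not used. Genes are therefore given by locus tag, with functions added as background from published work on this organism.

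Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr (minimum count 10), which left 4500, and libraries were scaled by TMM. Groups were compared with the quasi-likelihood test (two-sided), and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are AAGP over glucose. Levels are TMM-scaled CPM (counts per 1e6 counts), given as mean ± SD of 3 libraries. Genes that passed the test with a change of at least 4-fold were counted separately.

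The 29 gene lists are ranges of locus tags of known polysaccharide utilization loci (PULs), sugar utilization genes and capsule loci, with ranges recalled from published work. They were fixed, with the tests, the rule for named genes and most of the alternatives, before the data were examined. The 3 complex N-glycan loci among them had been reported by the study from these same samples. A further 32 lists that needed product names were not built. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and adjusted over the 29 lists. The same test with an estimated correlation and the rotation test fry stood beside it. Camera compares a list with all other genes, whereas fry asks whether the members move on balance in 1 direction. Shares of all counts were compared by an exact two-sided permutation test, which cannot fall below p = 0.1 with 3 libraries against 3.

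Named genes followed a fixed rule. It took the 8 largest rises and the 8 largest falls among genes that passed the test, did not overlap between groups in CPM and averaged at least 10 CPM. It added the 2 members with the largest change in the direction of each list that passed, and a fixed set of genes of N-glycan breakdown whatever their values. A part of the rule on SusC-like and SusD-like genes needed product names and was not applied. Other genes are named as examples of list members or of runs of neighbouring genes, and these were chosen after their values were seen.

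Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters, an adjusted p threshold of 0.01, a block on the replicate number and leaving out each library in turn. Removal of a trend with gene length, removal of a trend with chromosome position and a fit without the 6 structural RNA genes were added after the data were seen. The test was checked on simulated counts for the comparison of AAGP with glucose over 4500 genes, with 50 genes changed at each of 4 fold sizes. It recovered 94% of the genes changed 1.5-fold, 94% at 2-fold, 98% at 4-fold and 94% at 16-fold, with 17 calls among 4300 unchanged genes. Only 200 genes were changed there, in both directions, so it does not check the scaling or the test where most genes change. In a separate simulation of 29 lists, the 1 list that had been moved 2-fold passed the camera test and 0 others did. Genes were drawn independently there and nothing else was changed. It therefore does not check the preset correlation of 0.01 where genes of a list vary together. PCR reads without molecular identifiers are not independent molecules, so precision from the number of reads alone covers counting error only. The p-values and standard errors also take in the spread between tubes.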

Results

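Transcriptomes were obtained from 6 cultures of B. thetaiotaomicron VPI-5482 grown to mid exponential phase in minimal medium, 3 with glucose and 3 with AAGP as the carbon source. Total counts were 20288741, 17788244 and 22203011 in glucose replicates 1 to 3 and 29277332, 32305873 and 25758854 in AAGP replicates 1 to 3. Mean depth in units of 1e6 counts was 20.1 ± 2.21 on glucose and 29.1 ± 3.28 on AAGP (SD, n = 3), so the AAGP libraries were deeper. The 10 most abundant genes took between 11.22% and 11.47% of the counts in every library. Structural RNA genes took 1.69%, 1.60% and 1.67% of the counts on glucose and 3.01%, 2.58% and 2.28% on AAGP. No pair of libraries was alike within sampling noise. The chi-square per degree of freedom over genes was 6.21 to 7.20 for pairs on glucose, 28.8 to 41.0 for pairs on AAGP and 587 to 787 for pairs across the groups.

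The comparison of AAGP with glucose asked which genes differed between a serum glycoprotein with complex N-glycans and a simple sugar as the carbon source. AAGP brings protein as well as glycan, and was given at 10 mg/ml against 5 mg/ml of glucose. Effects of glycan, protein and amount cannot be told apart in this design. The largest rises lay in 1 locus, where BT_1042 went from 22.03 ± 1.77 to 9611 ± 1561 CPM (SD, n = 3), a 437-fold rise. The largest falls were in BT_3345, which was 30.5-fold lower on AAGP, and BT_3346, which was 27.3-fold lower. BT_2157 and BT_2158, from an operon described for the breakdown of glucosinolates, fell from 3867 ± 86.0 to 178 ± 9.31 CPM and from 2450 ± 20.01 to 115 ± 9.90 CPM. The neighbouring BT_2156 fell from 894 ± 25.2 to 44.0 ± 1.57 CPM, and BT_2178 fell from 794 ± 26.3 to 40.4 ± 3.01 CPM. BT_2119 was 16.9-fold lower.

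Of 4500 genes tested, 2937 (65.3%) changed between the carbon sources by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1509 higher and 1428 lower on AAGP. Counts of changed members in the lists below are to be read against these shares of all genes. A change of at least 4-fold was found for 92 genes higher on AAGP and 44 lower. The common biological coefficient of variation was 5.82%, so many small changes exceeded the spread between tubes. A small part of the variation in fold change, 4.66% of the variance of log2 fold changes bounded at 1 and -1, went with position on the chromosome. The median log2 fold change was 0.25 for the 381 genes between 1 and 1.5 Mb and -0.14 for the 352 genes between 4 and 4.5 Mb. With this trend removed, an alternative added after the data were seen, 2515 of the 2937 genes still passed the test in the same direction, and 88 genes were at least 4-fold higher and 43 at least 4-fold lower.

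**Figure D1:**
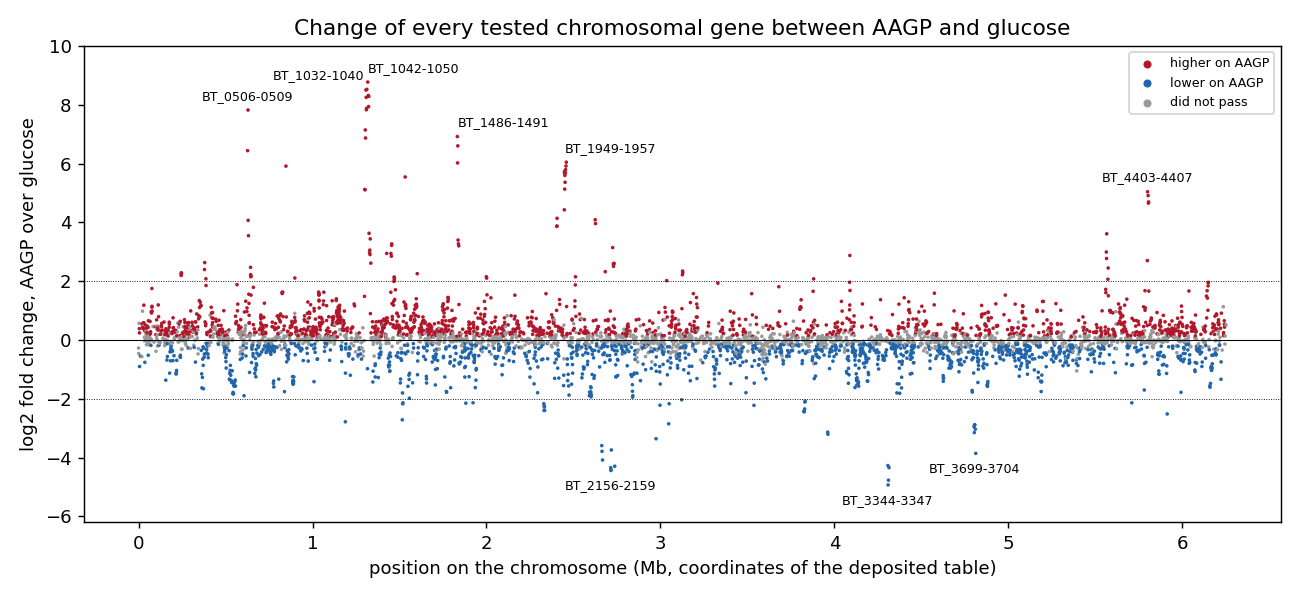
Log2 fold change (AAGP over glucose) of each tested chromosomal gene against its start on the chromosome in Mb, with red points for genes higher on AAGP, blue for genes lower and grey for genes that did not pass the test, and dotted lines at a 4-fold change. The highest points are genes of BT_1032 to BT_1050, up to 8.77, and the lowest is BT_3345 at -4.93.

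The 3 loci linked to complex N-glycans rose on AAGP. Together they took 0.214% ± 0.00307 of all counts on glucose and 4.62% ± 0.434 on AAGP (SD, n = 3). In BT_1032 to BT_1051, 19 of 20 genes rose, 18 of them at least 4-fold, with a median log2 fold change of 7.01. BT_1044, a family 18 endoglycosidase that cuts complex biantennary N-glycans from protein, rose 245-fold, from 7.13 ± 0.789 to 1741 ± 235 CPM. BT_1033, a family 130 phosphorylase acting on mannosyl-N-acetylglucosamine, rose 34.5-fold, from 63.2 ± 1.53 to 2181 ± 95.8 CPM. BT_1032 to BT_1051 had the largest share of the 3 loci on AAGP, at 3.95% ± 0.395 of the counts against 0.0346% on glucose.

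Other members of the same locus had comparable changes. Log2 fold changes were 8.52 for BT_1040, 8.50 for BT_1036, 8.31 for BT_1043, 8.28 for BT_1045, 8.25 for BT_1037 and 7.88 for BT_1039, with standard errors between 0.08 and 0.16. BT_1038 rose 228-fold and BT_1035 rose 117-fold. The change was smaller towards the end of the locus, where BT_1048 rose 8.32-fold, from 1.38 ± 0.0943 to 11.6 ± 2.80 CPM, and BT_1051 rose 1.86-fold. BT_1041, which lies between the oppositely oriented BT_1040 and BT_1042, fell by 0.98 on the log2 scale (SE 0.13). For BT_1042 the log2 fold change was 8.77 (SE 0.14), with an adjusted p of 8.99e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and it was higher in all 3 AAGP libraries than in any glucose library.

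**Figure D2:**
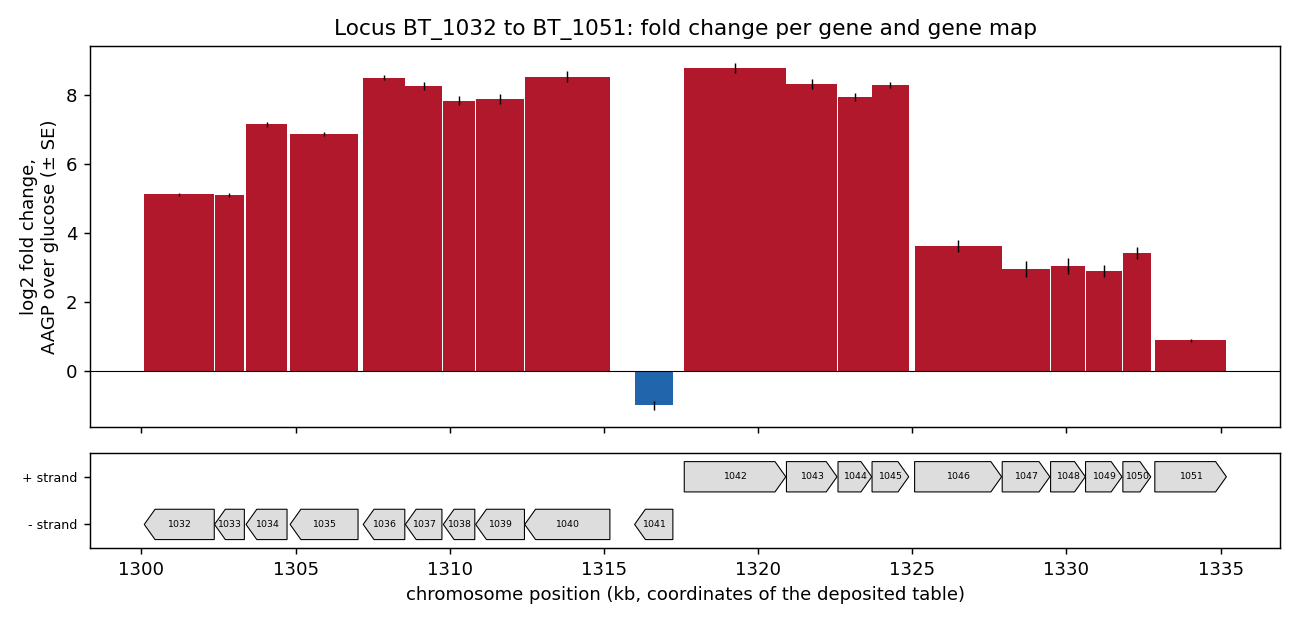
Upper panel: log2 fold change (AAGP over glucose, bars from 0, error bars ± SE, n = 3 per group) of the 20 genes from BT_1032 to BT_1051 against chromosome position in kb; lower panel: the genes drawn to scale on their strands. All bars but that of BT_1041, at -0.98, point upwards, and BT_1042 is the tallest at 8.77.

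The locus BT_4403 to BT_4407 (positions 5799518 to 5807973, plus strand) rose in all 5 genes, each at least 4-fold, with a median log2 fold change of 4.70. BT_4404 rose 32.9-fold, from 37.0 ± 0.187 to 1216 ± 157 CPM, and BT_4405 rose 30.05-fold, from 11.04 ± 0.137 to 332 ± 61.4 CPM (SD, n = 3). In BT_0455 to BT_0461 all 7 genes rose, by smaller factors and from a higher level on glucose. The sialidase BT_0455 rose 1.75-fold, from 323 ± 5.52 to 565 ± 40.2 CPM. The sialate O-acetylesterase BT_0457 rose 1.52-fold, the beta-mannosidase BT_0458 rose 1.54-fold and BT_0456 rose 1.47-fold. BT_0459 rose 3.68-fold, from 456.1 ± 15.9 to 1680 ± 170 CPM, and BT_0461 rose 2.33-fold.

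Adjusted over the list alone, the counts were the same as over all genes tested, with 19 higher and 1 lower, 5 higher, and 7 higher in the 3 loci. The study reported on these loci from the same samples, so neither these counts nor the list tests are independent evidence of their direction. Camera gave adjusted p = 1.96e-12 for BT_1032 to BT_1051, 1.33e-04 for BT_4403 to BT_4407 and 4.17e-04 for BT_0455 to BT_0461. With an estimated correlation between genes, none of the 3 passed (adjusted p = 0.315 for each with an estimated correlation). The exact permutation test of the shares of counts gave p = 0.1, the smallest that 3 against 3 libraries allow.

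**Figure D3:**
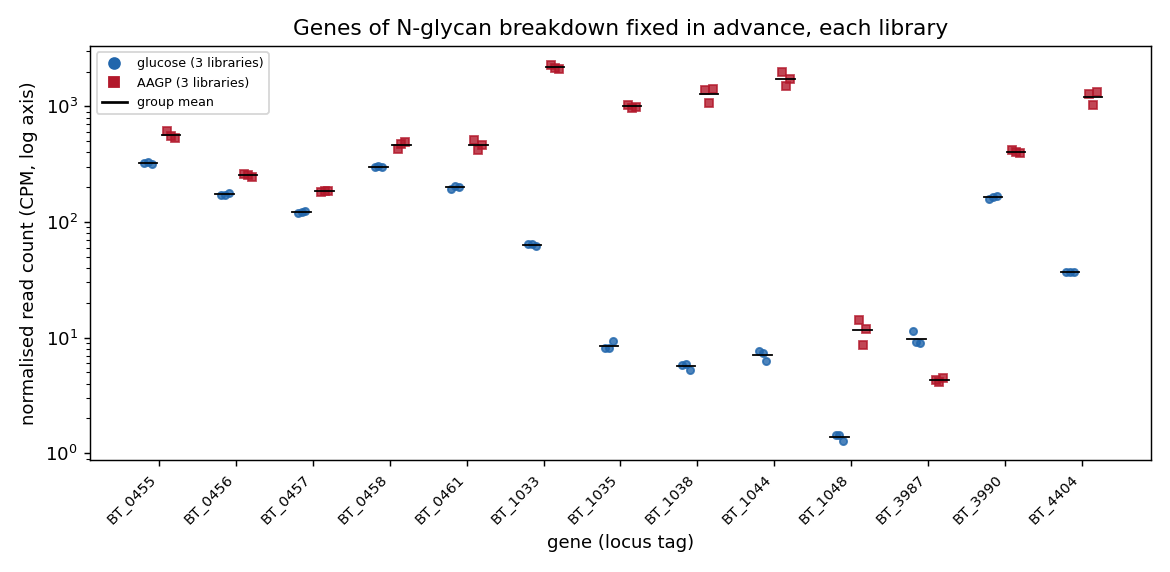
Normalised read count (CPM, log axis) of the 13 genes of N-glycan breakdown fixed in advance in each of 3 glucose libraries (blue circles) and 3 AAGP libraries (red squares), with group means as black lines. The AAGP values lie above the glucose values for every gene except BT_3987, whose means are 9.83 on glucose and 4.30 on AAGP.

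The PUL for high-mannose N-glycans, BT_3983 to BT_3994, was split between its members. Of 12 genes tested, 5 rose and 6 fell, and the same counts held adjusted over the list alone. BT_3990, a mannosidase of family 92, rose 2.48-fold, from 163 ± 5.41 to 405 ± 11.6 CPM (SD, n = 3), and BT_3992 rose 2.48-fold as well. BT_3987, an endoglycosidase that releases high-mannose glycans, fell from 9.83 ± 1.34 to 4.30 ± 0.141 CPM. BT_3983 to BT_3988 all fell, with BT_3984 lowest at a log2 fold change of -1.75, whereas BT_3989 had 0.07 and did not pass. The list as a whole did not pass camera (adjusted p = 0.891), with a median log2 fold change of -0.26 and a mean of -0.27. Fry gave the opposite sign, higher on AAGP, with adjusted p = 0.0214.

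The 3 PULs for yeast alpha-mannan changed in both directions, with no member changed at least 4-fold. In the first, 3 genes rose and 3 of 14 fell, with BT_2628 1.51-fold higher. In the next, 2 rose and 2 of 16 fell, and in the last, 4 rose and 1 of 10 fell. Adjusted over the list alone, the counts were 2 higher and 3 lower, 1 higher and 2 lower, and 4 higher and 1 lower. None passed camera, with adjusted p of 0.814, 0.891 and 0.660.

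All 6 genes of fucose utilization rose on AAGP. The fucose permease gene BT_1277 rose 2.06-fold, from 20.8 ± 2.23 to 42.8 ± 2.03 CPM, and the regulator gene BT_1272 rose 1.88-fold, from 58.7 ± 2.46 to 110 ± 3.42 CPM (SD, n = 3). In the arabinan PUL, 12 of 20 genes rose and 0 fell, with BT_0348 2.16-fold and BT_0352 1.91-fold higher. Those that did not pass include BT_0360 to BT_0364. The same counts held adjusted over the list alone. Camera gave adjusted p = 0.00705 for fucose utilization, whose median log2 fold change was 0.65, and 0.00358 for the arabinan PUL, whose median was 0.45. Neither passed with an estimated correlation (adjusted p = 0.315 for both with an estimated correlation).

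Among loci for host mucin O-glycans, 12 of 35 genes rose and 2 fell, and the same counts held adjusted over the list alone. Of all 4500 genes tested, 1509 rose. The 12 mucin genes that rose all lay in BT_4240 to BT_4250 and BT_4294 to BT_4300. The neighbours BT_4240, BT_4241 and BT_4242 rose 1.99-fold, 2.00-fold and 1.99-fold, with BT_4240 going from 295 ± 12.4 to 586 ± 29.3 CPM (SD, n = 3), while BT_3959 fell 2.03-fold. In the arabinogalactan PUL, 13 of 26 genes rose and 2 fell (12 and 2 adjusted over the list alone), with BT_0267 1.98-fold and BT_0289 1.85-fold higher. In the fructan PUL, 7 of 11 genes rose and 0 fell, among them the SusD-like gene BT_1762, 1.56-fold higher. In ribose utilization, 3 of 7 genes rose and 0 fell. Both of these counts were the same adjusted over the list alone. Camera gave adjusted p = 0.110 for the mucin loci, 0.0541 for arabinogalactan, 0.173 for fructan and 0.302 for ribose, so none passed. The mucin loci passed without AAGP replicate 2 (adjusted p = 0.0250) and with the position trend removed (adjusted p = 0.0365). Arabinogalactan passed without AAGP replicate 2 (adjusted p = 0.0391) and with the replicate block (adjusted p = 0.0483).

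The starch utilization system fell on AAGP. Of its 8 genes 7 fell, 6 of them at least 4-fold, with a median log2 fold change of -2.92. The neopullulanase gene susA (BT_3704) fell from 10.1 ± 0.103 to 0.684 ± 0.0968 CPM, 14.5-fold lower, and susE (BT_3700) fell from 17.0 ± 1.27 to 1.92 ± 0.453 CPM (SD, n = 3). The transporter gene susC (BT_3702) was 7.39-fold lower and susG (BT_3698), the gene of a surface amylase, was 2.18-fold lower. The regulator gene susR (BT_3705) rose 1.11-fold. The counts were the same adjusted over the list alone. Camera gave adjusted p = 4.17e-04 (adjusted p = 0.315 with an estimated correlation).

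In the PUL for chondroitin sulfate and hyaluronan, 13 of 27 genes fell and 3 rose, and the counts were the same adjusted over the list alone. The fall was largest in the neighbours BT_3344 to BT_3347 (positions 4308033 to 4315650, minus strand), each at least 4-fold lower. BT_3345 went from 30.5 ± 1.27 to 1.00 ± 0.0964 CPM, BT_3346 from 58.1 ± 0.766 to 2.13 ± 0.277 CPM, and BT_3347 was 20.3-fold lower (SD, n = 3). The median log2 fold change of the list was -0.09 and its mean -0.83. Camera gave adjusted p = 0.0217 (adjusted p = 0.450 with an estimated correlation). The list did not pass without AAGP replicate 3 (adjusted p = 0.0679) or with the position trend removed (adjusted p = 0.365).

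Other glycan PULs did not pass camera. In the heparin PUL 9 of 12 genes fell and 1 rose, with BT_4661 1.39-fold lower, and in the beta-1,6-glucan PUL 5 of 6 fell, with BT_3313 1.98-fold lower. Their adjusted p values by camera were 0.130 and 0.116, and heparin passed with the position trend removed (adjusted p = 0.0365). In the homogalacturonan PUL 3 genes rose and 5 of 17 fell, and in the rhamnogalacturonan I PUL 9 rose and 12 of 39 fell (adjusted p = 0.436 and 0.660). In the rhamnogalacturonan II PUL 9 rose and 12 of 52 fell (adjusted p = 0.891), with BT_0998 2.33-fold higher and BT_0988 2.30-fold lower. In the pectic galactan PUL 2 of 6 rose (adjusted p = 0.654). Adjusted over the list alone, the counts for heparin, beta-1,6-glucan, homogalacturonan and rhamnogalacturonan I were unchanged. They were 9 higher and 10 lower for rhamnogalacturonan II and 1 higher for galactan.

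**Figure D4:**
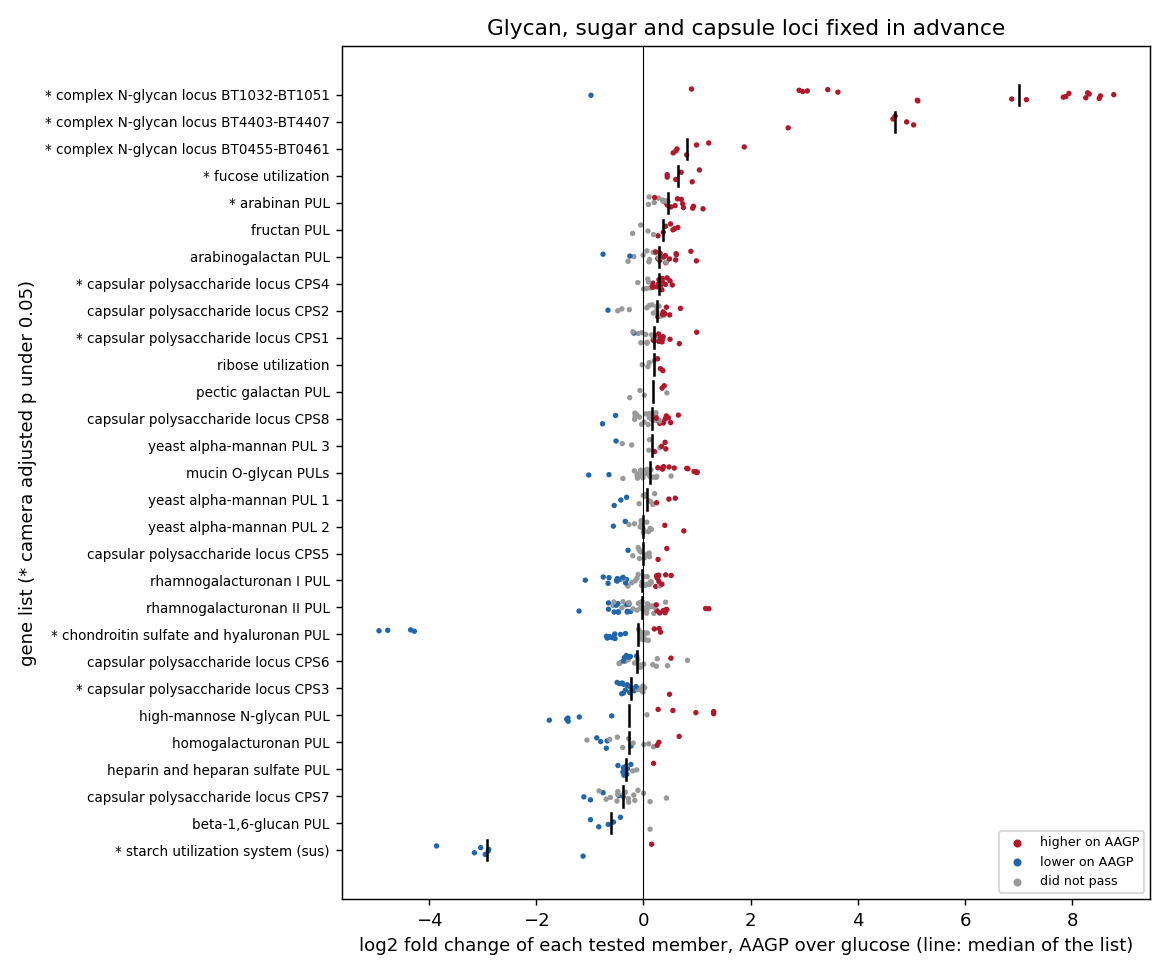
Log2 fold change (AAGP over glucose) of each tested member of the 29 lists fixed in advance, in red for genes higher on AAGP, blue for lower and grey for those that did not pass, with a black line at the median of each list and a star for lists with a camera adjusted p under the threshold. Medians run from -2.92 for the starch utilization system to 7.01 for BT_1032 to BT_1051, and 10 lists carry a star.

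Of the 8 capsular polysaccharide loci, whose products form alternative surface capsules, 3 passed camera with its preset correlation. These were CPS4, CPS1 and CPS3, and none of them passed with an estimated correlation (adjusted p = 0.450, 0.598 and 0.584 with an estimated correlation). In CPS4, the locus with the largest share of counts among them, 15 of 21 genes rose and 0 fell. BT_1346 rose 1.45-fold, from 204 ± 5.53 to 297 ± 31.9 CPM, and BT_1353 rose 1.41-fold (SD, n = 3). In CPS1, 17 of 28 genes rose and 1 fell (18 and 1 adjusted over the list alone), with BT_0401 1.99-fold and BT_0375 1.59-fold higher. BT_0401 is a gene of 219 bp on the minus strand that overlaps BT_0400, whereas BT_0400 and BT_0375 lie on the plus strand. In CPS3, 13 of 21 genes fell and 1 rose, with BT_0615 1.404-fold and BT_0613 1.36-fold lower. For CPS3 and CPS4 the counts were the same adjusted over the list alone.

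With the preset correlation camera gave adjusted p = 0.00345 for CPS4, 0.0152 for CPS1 and 0.0214 for CPS3. With the position trend removed, CPS4 and CPS1 did not pass (adjusted p = 0.121 and 0.181), whereas CPS3 had adjusted p = 3.89e-04. CPS3 did not pass without glucose replicate 2 (adjusted p = 0.0511) or without AAGP replicate 3 (adjusted p = 0.0556).

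The remaining 5 capsule loci did not pass camera. The genes that rose and fell were 7 and 1 of 21 in CPS2, 2 and 1 of 14 in CPS5, 1 and 6 of 23 in CPS6, 0 and 5 of 21 in CPS7, and 11 and 2 of 31 in CPS8. Adjusted over the list alone, they were 2 and 0, 2 and 0, 1 and 4, 0 and 2, and 9 and 2. Camera adjusted p values were 0.302, 0.888, 0.436, 0.170 and 0.224 in the same order. In all, 10 of the 29 lists passed, 7 higher and 3 lower on AAGP. The 7 include the 3 complex N-glycan loci that the study reported from these samples, which are not independent evidence. With an estimated correlation 0 passed, 2 had an unadjusted p under 0.05, and fry called 24.

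Many of the strongly changed genes lay outside the fixed lists, in runs of neighbours chosen after their values were seen. A run was taken as at least 3 neighbouring genes on 1 strand that all changed at least 4-fold in 1 direction. There were 14 runs higher on AAGP with 69 genes, and 6 runs lower with 27 genes. Only 3 of the higher and 2 of the lower runs lay in a fixed list. Of the 92 genes at least 4-fold higher, 23 were in fixed lists, and these 23 were all in the 3 complex N-glycan loci. A run outside the lists was BT_0506 to BT_0509 (positions 626800 to 633460, plus strand), with log2 fold changes between 3.55 and 7.82.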

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

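Removal of the length trend, removal of the position trend and the fit without structural RNA genes were chosen only after the results were seen. Changed genes kept between 2603 and 2807 of the 2937 calls when 1 library was left out, 2748 with DESeq2, 2515 with the position trend removed and 2418 at an adjusted p under 0.01, and 0 calls turned sign under any alternative. The 136 genes changed at least 4-fold still passed the test in their direction under each alternative, at any size of change, except that the filter of at least 10 CPM left 124 of them. Counts of genes at least 4-fold higher ran from 81 to 99 and lower from 43 to 49, with 88 and 43 when the position trend was removed. The replicate numbers did not pair the libraries (correlations of deviations -0.02, -0.05 and 0.01 for the same numbers), and a replicate block gave 2821 changed genes and 11 lists. The 42 named genes kept their sign and their side of the threshold under each alternative that tested them. The count of 10 lists became 0 with an estimated correlation and 24 with fry, which tests another question, and 9 with the position trend removed. The high-mannose PUL, which did not pass camera (adjusted p = 0.891), was called higher by fry (adjusted p = 0.0214), and the cause was not tested. Chondroitin sulfate, CPS1 and CPS4 no longer passed with the position trend removed (adjusted p = 0.365, 0.181 and 0.121). No scaling moved the median log2 fold change by more than 0.0358. Leaving out ribosomal RNA genes was not run, since none were recognised. The filter left out 331 genes with too few counts to test.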

Other observations

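The tests of the cobalamin loci against scaling, shared reads and cobalamin supply, the rotation of positions and the definition of the cobalamin lists were chosen only after the results were seen, and the position trend was itself noticed in these data.

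Genes of cobalamin (vitamin B12) uptake were among the most strongly raised on AAGP. All 6 genes of the first cobalamin locus, BT_1486 to BT_1491 (positions 1832520 to 1841546), rose at least 4-fold, with a median log2 fold change of 4.71. BT_1486 went from 23.6 ± 1.26 to 2851 ± 173 CPM and BT_1488 from 14.4 ± 1.32 to 1389 ± 71.3 CPM (SD, n = 3). All 9 genes of the second locus, BT_1949 to BT_1957 (positions 2448514 to 2460058), rose at least 4-fold, with a median of 5.68. These include BT_1953, the outer membrane transporter gene btuB2, which went from 15.7 ± 0.862 to 646 ± 13.1 CPM, and its surface partner btuG2 (BT_1954), with a log2 fold change of 5.68. The first and second loci took 0.722% ± 0.0231 and 0.794% ± 0.0300 of the counts on AAGP against 0.0282% and 0.0137% on glucose. The borders of both loci are those of runs of neighbours that all changed at least 4-fold. That every member rose at least 4-fold therefore follows from how the loci were cut. In the third locus 4 of 8 genes rose, 2 fell and 2 did not pass, and only BT_2094 and BT_2095 rose at least 4-fold, to 108 ± 8.56 and 122 ± 10.9 CPM. The largest log2 fold change in the third locus was 4.09 and the median 0.21. Its borders were not those of a run of 4-fold changes, so its counts are not comparable with those of the first 2 loci.

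A technical source of the rise in the first 2 cobalamin loci was sought. The 15 genes had been picked for rises of at least 4-fold, so large distances in the next 2 comparisons were fixed in advance. The genes lay a median of 5.70 above the length trend of the other genes on the log2 scale. That trend reached at most 0.0536 for them, too little to be the whole source. Scaling between libraries moves all genes alike. The lowest of the 15 log2 fold changes lay at least 3.20 above the median of all tested genes under 4 scalings, so a common factor was not the whole source. Reads shared between similar loci cannot be told apart from separate rises, because all 15 genes rose at least 4-fold and no sequences were used here. A lower supply of cobalamin in the AAGP cultures is a hypothesis that stays open, since 2 of the 8 genes of the third locus rose at least 4-fold, neither all nor none.

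The running median of the log2 fold change along the chromosome, over 1 Mb, peaked at 1.31 Mb (0.19) and was lowest at 3.79 Mb (-0.15), and a single wave fitted to log2 fold changes bounded at 1 and -1 accounted for 4.66% of the variance of 4463 genes. The larger distance of these points from the places where gene strand switches, at 1.098 and 3.75 Mb, was 0.212 Mb, and gene strands diverge at the latter. With 999 rotations of the genes around the chromosome, a share of 0.018 correlated as highly with a straight-line profile between the switches as the real order, which was included. The values argue against 1 library alone (lowest difference between an AAGP and a glucose library 0.169, largest within a group 0.0282). They also argue against genomic DNA in the libraries (amplitude among the most expressed of 3 equal groups of genes 1.13 times that among the least expressed). Without genes changed at least 4-fold, 0.870 of the amplitude remained. The bounds at 1 and -1 had already limited the weight of such genes, so this share alone cannot decide on a few strongly changed loci. Between 1 and 1.5 Mb, 55.6% of 381 genes rose and 15.5% fell, against 20.5% and 49.4% of 352 between 4 and 4.5 Mb. Shares this large argue against a few strongly changed loci as the whole source for the genes of these stretches. A candidate explanation is replication-linked gene dosage, with fewer copies near the replication origin relative to the terminus on AAGP, as slower growth would give, but growth rates were not used here.

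Short genes were slightly higher on AAGP. The median log2 fold change was 0.19 for 253 genes of up to 300 bp and -0.03 for 644 genes over 2000 bp, with a Spearman correlation with coding length of -0.10 across genes, which are not independent replicates. The slopes of expression on length differed by up to 0.0268 within a group, 0.733 of the difference between the groups. A difference in library preparation therefore cannot be told apart from an effect of the carbon source, and the biological explanation was not tested.

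Splits of the 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The real split gave 2937 changed genes, and the highest of the other splits gave 0 by edgeR (38 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For changes of at least 4-fold the real split gave 136 and the highest other 0, again 1 of 10. For the gene lists, 5 of 10 splits gave at least the 10 lists of the real split, and the highest other gave 16. Each of the other splits mixed libraries of both carbon sources, so the real difference widened the spread within their groups. Few gene calls were thus fixed in advance there, and these splits give no chance rate for genes or lists.

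Counts of the structural RNA gene EBG00001174547 were 25134 in AAGP replicate 1 against 7012 and 5756 in replicates 2 and 3. The median coefficient of variation on AAGP was 14.1% for the 20 genes of BT_1032 to BT_1051 and 5.02% for the 3307 genes of at least 10 CPM, and 17 of the 20 were highest in AAGP replicate 1.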
